A study of Mus musculus with 2 samples.

How the data were processed

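The sources used here are 2 droplet libraries of mouse mitral valve cells, 1 from 5 pooled wild type mice and 1 from 3 pooled Fbn1 C1039G/+ mice, all 1 month old. Valve tissue was digested with collagenases, dispase, elastase and hyaluronidase, and cells were captured with the 10x Genomics Chromium Single Cell 3′ kit, version 3.1. The values are raw UMI counts per gene and cell barcode, made by the authors with Cell Ranger on the mm10 genome and not normalised, per the file headers and labels. The submitters' notes name Cell Ranger 3.1.0 and the header of the count files names 5.0.1, and the counts alone did not settle which was run. The choice of barcodes that hold cells had been made before, and barcodes without a cell were not analysed here, so free RNA in the suspension was neither measured nor subtracted. Levels of genes of other cell types are given beside the results instead. Genes were placed on mm10 with GENCODE release M21 by Ensembl identifier, which matched 32235 of 32285 genes. Symbols that occur more than once were kept apart by identifier.

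Barcodes were kept with at least 500 genes, at least 1000 UMIs and at most 20% mitochondrial UMIs, which left 9190 wild type and 9440 Fbn1 C1039G/+ barcodes. Doublets were scored with Scrublet in scanpy, and an automatic threshold was used only where it called between 0.5% and 15% of barcodes. It called 0.011% and 0.021% here, so the barcodes with the highest scores were removed at the expected rate of 0.8% per 1000 barcodes (7.61% and 7.80%). This removed 751 and 776 barcodes, or 8.17% and 8.22%, with tied scores included. Counts were scaled to 10000 per cell and log transformed, 2000 variable genes, chosen with the library as batch, and 30 principal components were used, and cells were joined to 15 neighbours and clustered by the Leiden method at a resolution of 1 with a fixed seed. No integration of the libraries was used.

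Clusters were named from marker lists of 20 cell types. A marker counted when it was detected in at least 25% of the cells of a cluster and reached at least 20% of its highest cluster level, and at least 3 markers were needed. The lists were fixed in advance, while these thresholds and the rules for unnamed clusters were set after the data had been seen. A cluster was left unnamed when it held at least 60% of the markers of a second class, or when its 10 leading genes among genes in at least 80% of cells held more markers of another class than of its own. It was also left unnamed when its depth was under 50% of the library median and the same held among genes in at least 25% of cells. At 25% the deeper VIC-like clusters 2, 3 and 5 also have more leading markers of another class than of their own, and 1 alternative leaves these 3 out. Names carry the ending -like because they rest on transcripts alone.

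For each class with at least 100 cells in both libraries, UMIs were summed per library and expressed as CPM. Genes were measured when they had at least 20 CPM in either library and at least 50 UMIs over both, which gave 6518 genes in VIC-like, 7227 in VEC-like, 6062 in macrophage-like and 3968 in T cell-like cells. The log2 ratio used a pseudocount of 1 CPM. Levels have exact Poisson intervals, ratios exact conditional binomial intervals, shares exact Clopper-Pearson intervals and differences of shares Newcombe intervals, all at 95%. No p-value was computed, because 1 library per genotype leaves no replicate. A count of 0 was set at a floor of 3 counts over the class in that library.

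Before the data were examined, the gene lists, cell type markers, filters, comparisons, most alternatives and the rule for named genes were fixed. In VIC-like cells the rule named the 10 genes with the largest and the 10 with the smallest log2 ratio among measured genes whose interval excluded 1. In the other classes it named 5 and 5. Of the 20 genes at either end in VIC-like cells 1 is not reported here. It left out mitochondrial, ribosomal protein, hemoglobin, immunoglobulin and T cell receptor genes, Xist, Tsix, Y-linked genes and gene models. It added up to 4 members of each list, of which the text gives some, Fbn1, Tgfb1, Tgfb2, Tgfb3 and Ccr2, and Xist and Y-linked genes to check the sexes in the pools. Genes named outside this rule, among them list members counted by the 1.5-fold rule, Col1a1, Col3a1, C1qa, Hbb-bs, Igkc, Il1b and Ifit1, were chosen after their values were seen.

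There were 27 gene lists, 17 set for VIC-like cells, 4 for VEC-like cells and 6 for macrophage-like cells. The 17 covered fibrillin and elastic fibre, collagens, proteoglycans and hyaluronan, TGF-beta, BMP and Wnt pathways, matrix proteases and inhibitors, contractile and myofibroblast genes, chondrogenic and osteogenic genes, and chemokines, cytokines and adhesion. They also covered complement, interferon response, cell cycle, dissociation and immediate early genes, oxidative phosphorylation, glycolysis and hypoxia, and endoplasmic reticulum stress and folding. The 4 covered shear stress and nitric oxide, the Notch pathway, lymphatic-type valve endothelium and endothelial-to-mesenchymal transition. The 6 covered antigen presentation by MHC class II, resident macrophage, monocyte-derived macrophage, macrophage inflammatory mediators, lipid and lysosome macrophage, and complement C1q and phagocytosis. A list median has a counting interval from 1000 Poisson redraws and a percentile among 10000 random lists of the same size, matched in 20 bins of expression, as a description of these libraries only. The division of the dissociation list into 14 immediate early and 6 heat shock members was made after its values were seen.

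VIC-like cells were clustered again at a resolution of 0.5, and then without genes that differed at least 1.5-fold, since such genes otherwise define clusters that then differ in size. Cells were called female or male from Xist and Y-linked transcripts. The comparison step was tested on simulated counts in which 200 genes were changed by 1.5-fold, 2-fold or 4-fold. It called 100% of 2-fold changes in VIC-like, VEC-like and macrophage-like cells and 92.1% in T cell-like cells. It called 37.3% to 54.5% of 1.5-fold changes, which lie at the threshold. Of unchanged genes it called none in VIC-like and macrophage-like cells, 0.159% in VEC-like and 2.39% in T cell-like cells. The simulation held counting error only.

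Alternatives changed 1 choice at a time, apart from the looser cell filter. They were a looser cell filter (200 genes, 500 UMIs, 30%), a stricter one (1000, 2000, 10%), doublets kept, Leiden resolutions of 0.5 and 2 for all cells and of 0.3 and 1 for VIC-like cells, and each library clustered alone. Others were TMM scaling, median-ratio scaling, the mean of per-cell CPM, cells thinned to 2000 UMIs, no level filter, a level filter of 100 CPM and a pseudocount of 10 CPM. The alternative without VIC-like clusters 2, 3 and 5 and the clustering without differing genes were chosen after seeing the data. In the looser filter the automatic doublet threshold of the wild type library called 2.52% and was used, while 8.64% were removed by top scores in the Fbn1 C1039G/+ library, so this alternative joins a change of filter and of doublet rule. Dendritic cell-like and melanocyte-like cells, with fewer than 100 cells in 1 library, and 24 and 122 cells in unnamed clusters entered no comparison of single genes. In dendritic cell-like and melanocyte-like cells only medians of the immediate early, heat shock and interferon genes were taken. Software was Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.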

Results

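Single-cell 3′ RNA libraries were made from mitral valves of mice at 1 month of age, 1 library from 5 pooled wild type mice and 1 from 3 pooled Fbn1 C1039G/+ mice. Fbn1 encodes fibrillin-1, the main protein of extracellular microfibrils, and C1039G replaces a cysteine of that protein, which gives a mouse model of Marfan syndrome. The mitral valve separates the left atrium from the left ventricle, and its leaflets hold interstitial cells that make the matrix, an endothelial covering and immune cells. The wild type library held 100969482 unique molecular identifiers (UMIs) in 9509 barcodes, and the Fbn1 C1039G/+ library held 103663375 in 9744. After filtering and removal of predicted doublets, 8439 and 8664 cells were kept, with a median of 9753 and 9723.5 UMIs and of 3225 and 3254 genes per cell. Reads of mitochondrial genes made up a median of 3.41% and 3.36% of UMIs.

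Each genotype had 1 library, so there was no replicate against which to set a difference, and cells of a library were not treated as replicates. Values are therefore given for both libraries, with 95% intervals that cover counting error only and no variation between mice, dissections or library preparations. Levels are in CPM, the UMIs of a gene scaled to a fixed total for each cell class and library, and log2 ratios are Fbn1 C1039G/+ over wild type. A member of a gene list was counted as higher or lower when its ratio was at least 1.5-fold in either direction and its counting interval excluded 1. The Fbn1 C1039G/+ pool of 3 mice held both sexes, so 1 sex in it came from a single mouse. Values given by sex therefore cannot be told apart from differences between single mice.

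The first comparison asked how much Fbn1 transcript each library held in the valve cell classes. Fbn1 (ENSMUSG00000027204; mm10 chromosome 2, 125300594 to 125507993, minus strand) was similar in valve interstitial-like (VIC-like) cells of both libraries, at 422 CPM (417 to 426) in the wild type and 461 CPM (456 to 466) in the Fbn1 C1039G/+ library. The ratio was 1.09 (1.08 to 1.11), from 30546 and 34334 UMIs. In valve endothelial-like (VEC-like) cells Fbn1 stood at 122 and 136 CPM, with a ratio of 1.12 (0.995 to 1.25). Macrophage-like cells held 23.7 and 18.3 CPM. The genes of the TGF-beta ligands, which fibrillin microfibrils help to hold in the matrix, also had similar levels in VIC-like cells. Tgfb1 stood at 44.7 and 51.8 CPM, Tgfb2 at 120.3 and 138 CPM and Tgfb3 at 120.4 and 113 CPM. The counts come from the 3′ ends of transcripts and could not separate the C1039G allele from the wild type allele, so the level of Fbn1 is no check of the genotype.

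The second comparison asked which cell classes made up each library. VIC-like cells, the matrix-making fibroblasts of the valve, were the main class in both, at 82.5% (81.7 to 83.3) of kept wild type cells and 80.2% (79.3 to 81.0) of Fbn1 C1039G/+ cells, a difference of -2.32 percentage points (-3.48 to -1.15). VEC-like cells made up 3.25% and 4.69%, a difference of 1.44 points (0.855 to 2.03). Macrophage-like cells made up 9.73% and 10.4%, with an interval of the difference from -0.232 to 1.57 points. T cell-like cells made up 1.72% and 1.24%, a difference of -0.483 points (-0.851 to -0.122). Dendritic cell-like cells numbered 99 and 111 and melanocyte-like cells 115 and 71, too few in 1 of the libraries for a comparison of genes. Digestion and capture also set these shares, and with 1 library per genotype that part could not be measured.

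The third comparison asked which genes differed by genotype in VIC-like cells, from 72455537 and 74512376 UMIs in 6961 and 6946 cells. The clearest differences were lower immediate early and inflammatory transcripts and higher interferon-stimulated transcripts in the Fbn1 C1039G/+ library. Fos, a transcription factor gene switched on within minutes of a stimulus (ENSMUSG00000021250; chromosome 12, 85473890 to 85477273), stood at 1361 CPM in the wild type and 497 CPM in the Fbn1 C1039G/+ library, a ratio of 0.365 (0.361 to 0.370). Isg15, a ubiquitin-like protein gene induced by interferon (ENSMUSG00000035692; chromosome 4, 156199424 to 156200818), stood at 107 and 229 CPM, a ratio of 2.15 (2.09 to 2.21). Most matrix genes differed far less, and the collagen genes were slightly higher together. Across the 6518 genes measured in VIC-like cells the median log2 ratio was 0.034.

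The 10 largest ratios in VIC-like cells included the interferon-stimulated genes Ifi44 (6.36 and 27.5 CPM; ratio 4.32, interval 3.91 to 4.79), Bst2 (189.6 and 411 CPM; 2.17, 2.13 to 2.21) and Isg15. Also among them were the inducible heat shock genes Hspa1a (36.2 and 85.5 CPM) and Hspa1b (13.6 and 38.9 CPM), and Fst, which encodes the activin-binding protein follistatin (16.7 and 46.0 CPM). Cst6 and Serpina3n, which encode protease inhibitors, had log2 ratios of 1.31 and 1.10, and Ttc9 1.21. The 10 smallest ratios were led by Gadd45b, a stress-induced gene (135 and 26.3 CPM; ratio 0.195, 0.185 to 0.204), the neutrophil chemokine gene Cxcl1 (49.0 and 11.4 CPM) and the matrix protein gene Coch (24.1 and 5.78 CPM). They also held Zfp36 (log2 ratio -1.63), Fosb (-1.59), Atf3 (-1.52), Ppp1r15a (-1.51), Socs3 (-1.50), Fos (-1.45) and Sez6l (-1.21).

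**Figure D1:**
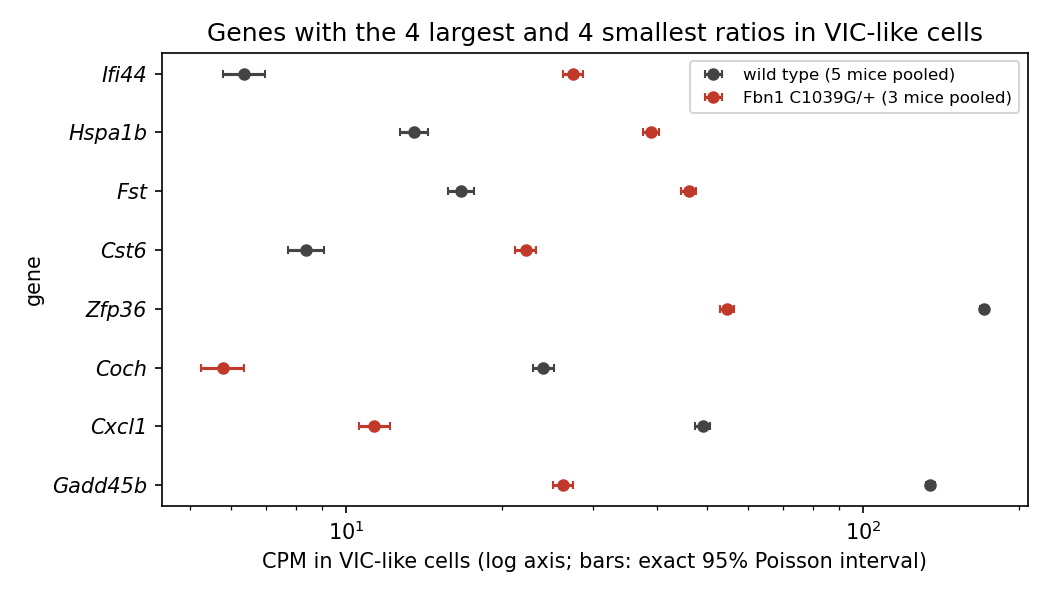
Levels of the genes with the 4 largest and the 4 smallest ratios in VIC-like cells, in CPM on a log axis, with exact 95% Poisson intervals that cover counting error only. The upper 4 genes were higher in the Fbn1 C1039G/+ library and the lower 4 were lower, from Ifi44 at 6.36 and 27.5 CPM to Gadd45b at 135 and 26.3 CPM.

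Of the matrix lists, the 19 measured collagen genes had a median log2 ratio of 0.24 (0.22 to 0.27), at percentile 100 of 10000 random lists matched on level, a rank that describes these libraries only. All 19 ratios were above 0 on the log2 scale, from 0.03 for Col6a2 upwards. By the 1.5-fold rule 1 was higher, the short-chain collagen gene Col8a1 (ENSMUSG00000068196; chromosome 16, 57624258 to 57754737), at 91.4 and 173 CPM. Col18a1 had a log2 ratio of 0.43, Col5a3 0.38 and Col14a1 0.32. The main fibrillar collagen genes stood at 3564 and 4394 CPM for Col1a1 and 3778 and 4652 CPM for Col3a1. Of 20 fibrillin and elastic fibre genes 1 was lower, Efemp1 (36.3 and 21.4 CPM), and the median was 0.077 (0.049 to 0.114). Mfap4, a microfibril-associated gene, stood at 1383 and 1008 CPM, and Ltbp1, which encodes a latent TGF-beta binding protein, at 73.4 and 101 CPM. Fbn2, the gene of the second fibrillin, stood at 33.4 and 44.4 CPM. Of 16 proteoglycan and hyaluronan genes 1 was lower, Chad (147 and 84.2 CPM), with a median of 0.018, or -0.050 without a level filter. By sex 2 were higher and 2 lower of 16 in female cells (median 0.013), and none of 17 passed in male cells (median 0.081). In the same list Prg4, the lubricin gene, stood at 2361 and 1654 CPM and Vcan, the versican gene, at 797 and 1059 CPM. Matrix proteases and their inhibitors had 1 member higher and 2 lower of 16 and a median of 0.13. Without a level filter it was 0.0096, and by sex it was -0.043 in female and 0.22 in male cells. The higher one was Timp1, an inhibitor of matrix metalloproteinases (ENSMUSG00000001131; chromosome X, 20870166 to 20874735), at 228 and 411 CPM, and the lower ones were Adamts1 (54.4 and 33.3 CPM) and Htra3 (340.2 and 219 CPM).

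None of the 22 measured members of the TGF-beta list passed the 1.5-fold rule in VIC-like cells, and the list median was 0.088 (0.056 to 0.120). In female cells 4 of 22 were higher (median 0.094) and in male cells none (median 0.039). Its 4 most different members were all TGF-beta targets with higher levels in the Fbn1 C1039G/+ library. Ccn2 stood at 491 and 721 CPM, Tgfbi at 325 and 468 CPM, Postn at 1688 and 2376 CPM and Thbs1 at 1376 and 1905 CPM. In the contractile and myofibroblast list none of 12 members passed either, with a median of 0.16 (0.14 to 0.18). In it Tagln stood at 449 and 636 CPM, Actn1 at 138 and 190.1 CPM and Acta2 at 301 and 360.1 CPM. In the BMP list none of 15 passed, with a median of 0.028 (-0.043 over members with at least 100 CPM, 0.027 in female and -0.054 in male cells) and Msx1 at 89.6 and 63.0 CPM. The Wnt list had 1 member lower of 14, Wnt9a (31.0 and 16.1 CPM), and a median of -0.013. Chondrogenic and osteogenic genes had 1 member lower of 11, Spp1 (20.1 and 10.8 CPM), and a median of 0.018, while the same median was 0.15 with thinned cells. Scx, a tendon transcription factor gene, stood at 209.6 and 291 CPM.

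Of 17 interferon-response genes 6 were higher and none lower, with a median of 0.32 (0.28 to 0.36) at percentile 100 of the random lists, or 0.66 over members with at least 100 CPM. Beside Ifi44, Bst2 and Isg15 these were Irf7 (26.3 and 55.7 CPM), Ifi27l2a (695 and 1099 CPM) and Gbp3 (13.9 and 20.99 CPM). Ifit1, another interferon-induced gene, was alike in both libraries, at 70.5 and 68.7 CPM. Within single VIC-like clusters the list median ranged from -0.25 in cluster 17 to 0.62 in cluster 4. Of 13 chemokine, cytokine and adhesion genes 4 were lower and none higher, with a median of -0.39. By sex the median was -0.10 (-0.19 to -0.029) in female cells, with 2 higher and 3 lower of 12, and -0.33 in male cells, with 7 lower of 15. They were Cxcl1, Ccl19, Cxcl10 (44.8 and 24.9 CPM) and Nfkbia (186 and 118 CPM). The Ccl19 gene counted here (ENSMUSG00000071005) shares its symbol with near-identical copies, so its level is uncertain. Complement genes had 2 members lower of 7, C3 (99.2 and 42.9 CPM) and C1s1 (32.5 and 17.8 CPM), and a median of -0.26, or -0.42 without VIC-like clusters 2, 3 and 5, and -0.44 in female and -0.15 in male cells. Clu, an inhibitor of complement, stood at 464 and 691 CPM. Macrophage transcripts were low in VIC-like cells, with C1qa at 8.34 and 13.3 CPM and Lyz2 at 13.1 and 17.7 CPM.

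Of the 20 measured genes of the dissociation and immediate early list 10 were lower and 2 higher, with a median of -0.60 (-0.62 to -0.59) at percentile 0 of the random lists. These genes respond to enzymatic digestion of tissue as well as to growth factors and stress. The lower ones were Zfp36, Fosb, Atf3, Socs3, Fos, Btg2, Nr4a1, Junb, Ier3 and Egr1, of which Junb stood at 1134 and 568 CPM and Egr1 at 808 and 494 CPM. The higher ones were Hspa1a and Hspa1b. Over the 14 immediate early members alone the median was -1.05 (-1.07 to -1.03). It was below 0 in each VIC-like cluster, from -0.58 in cluster 0 to -1.76 in cluster 5. Glycolysis and hypoxia had 1 member lower of 16, the angiogenic factor gene Vegfa (66.6 and 29.8 CPM), and a median of 0.087. None of 19 endoplasmic reticulum folding genes passed the rule (median 0.15), none of 22 oxidative phosphorylation genes (0.052) and none of 7 cell cycle genes (0.055, or -0.12 with doublets kept). The cell cycle value joined opposite directions by sex, with 4 of 9 members higher and a median of 0.51 in female cells and a median of -0.34 in male cells. Ddit3, a stress gene of the folding list, stood at 46.8 and 63.5 CPM, though its symbol is also repeated in the annotation. By sex-linked transcripts 47.0% and 48.7% of VIC-like cells were female and 42.2% and 39.3% male, so both pools held both sexes, with Xist at 448 and 467 CPM.

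VIC-like cells of both libraries lay in the same clusters, but in unequal shares. Cluster 5 of all kept cells held 1230 wild type and 545 Fbn1 C1039G/+ cells, while cluster 0 held 306 and 1080 and cluster 6 held 220 and 705. Each VIC-like ratio given here therefore joins differences within cell states with differences in their shares. Collagen medians within clusters ranged from 0.0033 in cluster 3 to 0.42 in cluster 15.

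**Figure D2:**
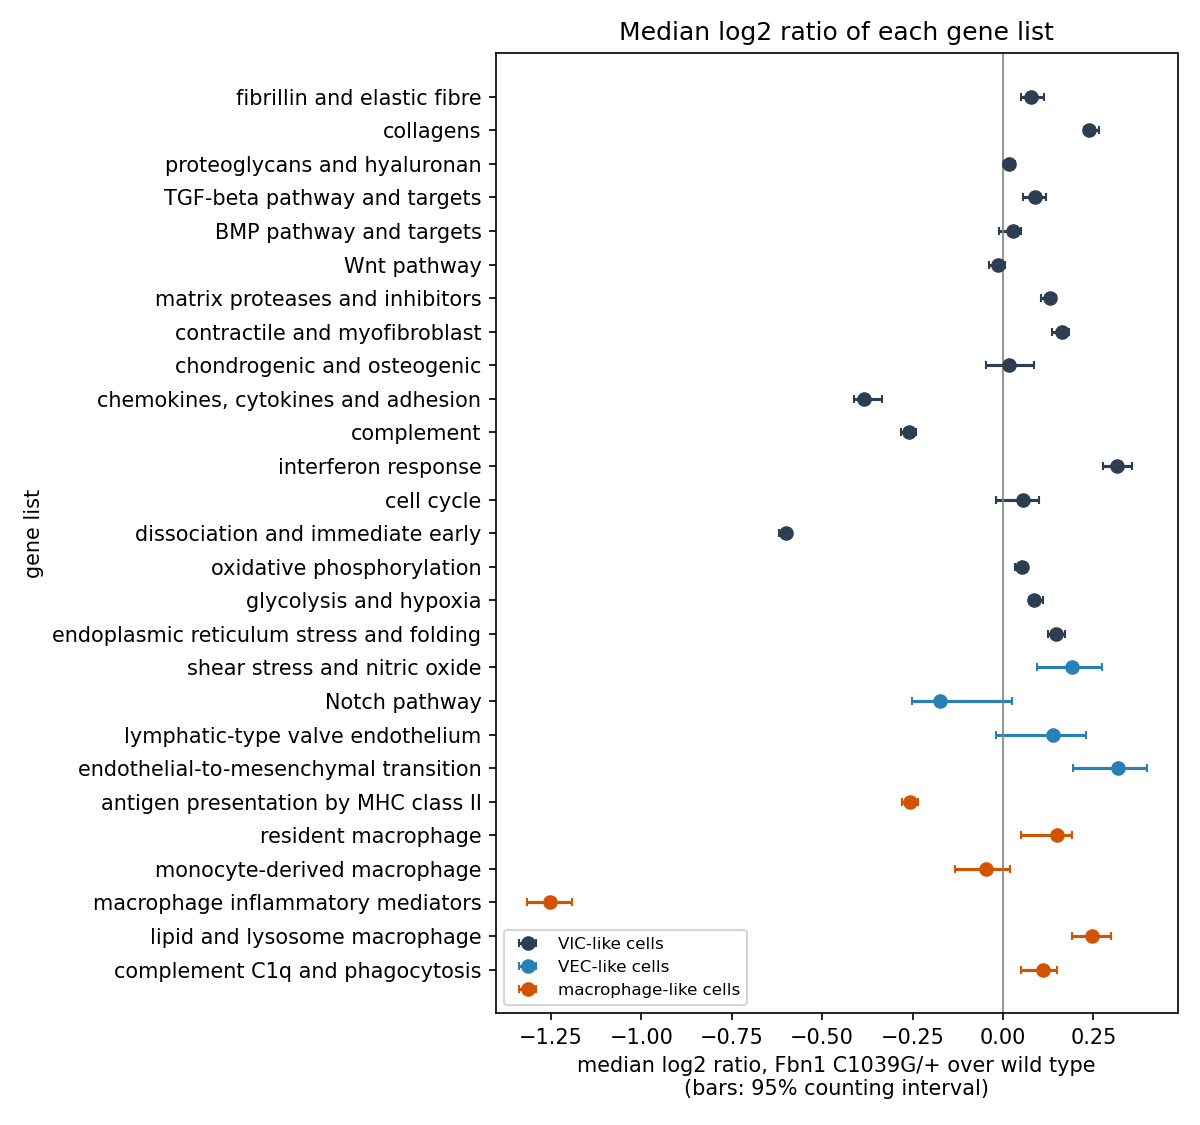
Median log2 ratio of each gene list in the class it was set for, with 95% counting intervals, for VIC-like, VEC-like and macrophage-like cells. Macrophage inflammatory mediators (-1.25) and dissociation and immediate early genes (-0.60) lay farthest below 0, and endothelial-to-mesenchymal transition (0.32) and interferon response (0.32) farthest above.

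The fourth comparison asked how VIC-like cells divided into states in each library. Since genes that differ between the libraries would themselves split the cells by library, the division described here was built without genes that differed at least 1.5-fold, a choice made after the values were seen. Among its 9 clusters the largest differences were in cluster 6, led by the Wnt agonist gene Rspo3 and the vascular growth factor gene Angpt1, with 26.7% (25.7 to 27.7) of wild type and 17.0% (16.1 to 17.9) of Fbn1 C1039G/+ VIC-like cells. Cluster 0, led by Car3, Vcan and Postn among others, held 14.3% (13.5 to 15.1) and 23.2% (22.2 to 24.2). Rspo3 (124 and 83.6 CPM), Vcan and Postn differed by under 1.5-fold and so still entered the division they lead. Cluster 3, led by the interferon-induced genes Ifit3 and Ifit1, held 2.39% and 6.44%. Cluster 2, led by Mmp3 and Svep1, held 17.1% and 12.9%, and cluster 1, led by Notch3, 8.53% and 6.21%. Cluster 7, led by Thbs4 and Cspg4, held 10.8% and 13.02%. Cluster 4, led by the cartilage-type genes Cilp2 and Comp, held 19.3% and 18.4%, and proliferating cells led by Top2a made up 0.919% and 1.34%. Cluster 5 held 0.072% and 1.53%, with a median of 1815 UMIs per cell and mt-Cytb among its leading genes. The index of dissimilarity, the share of cells that would have to move between clusters to make both libraries alike, was 17.0 percentage points (15.5 to 18.6). When cells were redrawn without a difference the index had a median of 1.69 and reached at most 3.71, which measures sampling of cells and not variation between mice.

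**Figure D3:**
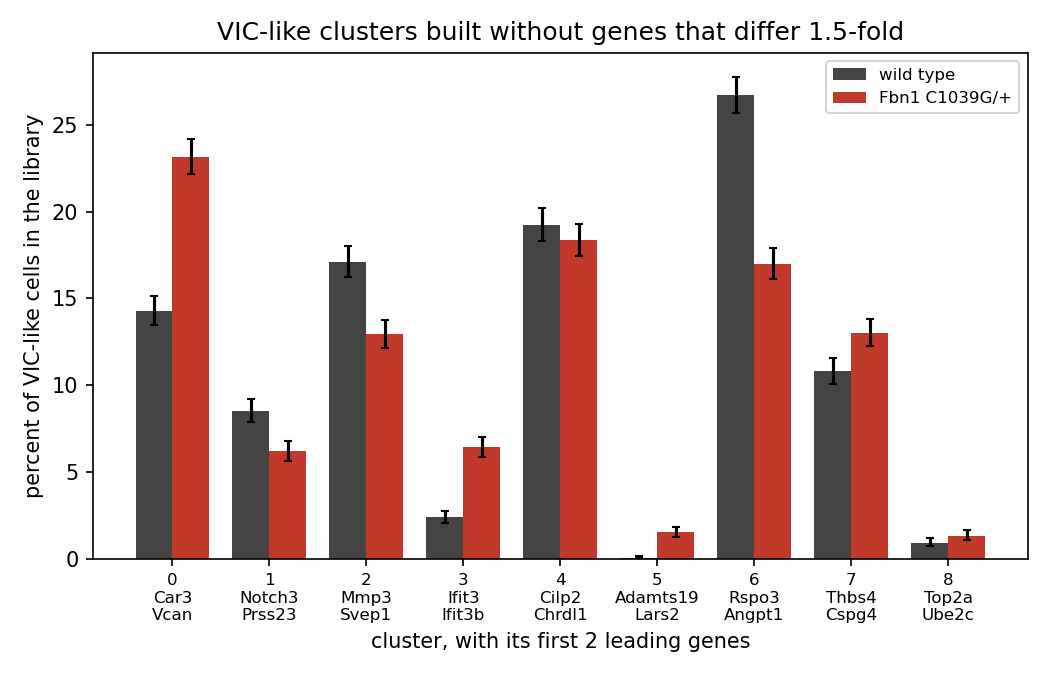
Percent of VIC-like cells in each of 9 clusters for the wild type and Fbn1 C1039G/+ libraries, with exact 95% Clopper-Pearson intervals for counting error and the first 2 leading genes under each cluster number. Cluster 6 held 26.7% of wild type and 17.0% of Fbn1 C1039G/+ cells, and cluster 0 held 14.3% and 23.2%.

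The fifth comparison asked the same of VEC-like cells, from 3824104 and 5954676 UMIs in 274 and 406 cells. Some genes abundant in interstitial cells and 5 of 17 genes of endothelial-to-mesenchymal transition were higher in the Fbn1 C1039G/+ library, and Ccl21a, Mmrn1 and Reln were present almost only in the wild type library. Ecrg4, a secreted peptide gene abundant in VIC-like cells (ENSMUSG00000026051; chromosome 1, 43730602 to 43742578), stood at 15.2 and 170.1 CPM, a ratio of 11.2 (8.61 to 14.9). Col12a1, a collagen gene (ENSMUSG00000032332; chromosome 9, 79598991 to 79718831), stood at 10.98 and 91.4 CPM, a ratio of 8.32 (6.07 to 11.7). Ccl21a, a chemokine gene of lymphatic vessels, stood at 430.2 CPM in the wild type and had no UMI in the Fbn1 C1039G/+ library. It was 854-fold lower against a floor of 3 counts, with a ratio interval up to 0.0014.

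The other genes at the upper end in VEC-like cells were Nppb, a natriuretic peptide gene (1.83 and 24.2 CPM), Nrtn (3.66 and 29.9 CPM) and Sfrp2, a secreted Wnt modulator gene (2.35 and 20.99 CPM). The 5 Fbn1 C1039G/+ cells with most UMIs of a gene held 70.4% of them for Sfrp2, 50.7% for Nppb, 47.2% for Nrtn, 45.4% for Ecrg4 and 36.2% for Col12a1. At the lower end stood Mmrn1 (85.0 and 0.336 CPM), Reln (20.4 and 0 CPM, ratio interval up to 0.0311), Maf (54.9 and 5.54 CPM) and Nrp2 (82.4 and 11.8 CPM). The Ccl21a gene (ENSMUSG00000094686) also shares its symbol with near-identical copies. In the wild type library 4 of 274 VEC-like cells held 2047 of the 2048 UMIs of Mmrn1, Ccl21a and Reln. No such cell was among the 406 of the Fbn1 C1039G/+ library, which allows a share of up to 0.904%. Without the 4 cells Maf stood at 7.10 and 5.54 CPM and Nrp2 at 31.7 and 11.8 CPM.

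Of 17 endothelial-to-mesenchymal genes in VEC-like cells 5 were higher and none lower, with a median of 0.32 (0.19 to 0.40), or 0.26 without the 4 lymphatic-type cells. This median was 0.042 with cells thinned to 2000 UMIs and 0.096 over members with at least 100 CPM, and by sex it was 0.087 (-0.056 to 0.25) in female and 0.23 (0.10 to 0.35) in male cells. The 5 higher genes were Cdh2, the N-cadherin gene (4.71 and 26.2 CPM), Sox9 (3.66 and 20.2 CPM), the smooth muscle actin gene Acta2 (22.5 and 83.3 CPM), Tagln (6.80 and 21.2 CPM) and S100a4 (57.8 and 141 CPM). In the Fbn1 C1039G/+ library 5 of the 406 cells held 57.9% of the Acta2 UMIs, with 34.5% in 1 cell, and the 5 cells with most held 46.8% for Tagln, 42.5% for Sox9 and 28.2% for Cdh2. Some other transcripts of interstitial cells and blood were also higher in this class, with Col1a1 at 52.6 and 213 CPM, Col3a1 at 274 and 542 CPM and the hemoglobin gene Hbb-bs at 23.5 and 413 CPM, while Abi3bp stood at 57.0 and 50.7 CPM. Some lists set for other classes shifted more than the transition list in VEC-like cells. Medians were 0.98 for collagens (7 of 13 higher), 0.79 for cell cycle (11 of 17 higher) and 0.50 for contractile genes. Macrophage inflammatory mediators had 1.36 (3 of 5 higher). Medians below 0 included those of MHC class II (-0.74) and Wnt genes (-0.17). Shear stress and nitric oxide genes had 2 members higher of 15, Adm (16.5 and 38.5 CPM) and Cyp1b1 (13.6 and 20.7 CPM), and a median of 0.19, or 1 higher and 0.13 without the 4 cells. Their median was 0.0090 with thinned cells and 0.079 when each cell had equal weight, and 0.036 in female and 0.20 in male cells. In that list Thbd, the thrombomodulin gene, stood at 351 and 503 CPM. The Notch list had 1 member higher and 1 lower of 9, Efnb2 (245 and 406 CPM) and the ligand gene Dll1 (45.0 and 26.2 CPM), and a median of -0.17 (-0.25 to 0.024) that changed to 0.15 over members with at least 100 CPM. The lymphatic-type valve endothelium list had 4 members higher and 2 lower of 11, with a median of 0.14 that was the same with Ccl21a set at its bound. By sex this median was -0.045 (-0.11 to 0.062) in female and 0.30 (0.090 to 0.41) in male cells. The higher ones were Foxc2 (90.5 and 159 CPM), Nts (678 and 1156 CPM), Prox1 (199 and 328 CPM) and Cldn11 (63.3 and 101 CPM), and the lower ones Ccl21a and Lyve1 (20.9 and 2.52 CPM). Without the 4 cells this list had 4 higher and 0 lower of 9. The direction of Adm turned when each cell had equal weight (log2 ratio -0.15).

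The sixth comparison asked the same of macrophage-like cells, from 7927990 and 7267350 UMIs in 821 and 901 cells. Inflammatory cytokine and chemokine transcripts were lower in the Fbn1 C1039G/+ library, and few members of the resident, lipid-handling and phagocytic macrophage lists passed the 1.5-fold rule, all of them higher. Cxcl2, a neutrophil chemokine gene (ENSMUSG00000058427; chromosome 5, 90903871 to 90905938), stood at 3777 and 709 CPM, a ratio of 0.188 (0.182 to 0.193). Il1b, the interleukin-1 beta gene, stood at 479 and 136 CPM. Of 19 inflammatory mediators 12 were lower and none higher, with a median of -1.25 (-1.32 to -1.19) at percentile 0 of the random lists.

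Beside Cxcl2 and Il1b the lower mediators in macrophage-like cells were Ptgs2, the cyclooxygenase gene (27.9 and 2.61 CPM), Tnfaip3 (126 and 20.5 CPM), Cxcl1 (208 and 35.1 CPM), Tnf, Il1a, Nlrp3, Nfkbia, Ccl3, Ccl4 and Ccl8. The 14 immediate early genes had a median of -1.33 in this class. Library preparation and genotype cannot be told apart as causes of the lower mediators, because each genotype was prepared as 1 library. Resident macrophage genes had 2 members higher of 13, Fcna (27.1 and 42.7 CPM) and Lyve1 (74.7 and 115 CPM), and a median of 0.15 that was 0 when each cell had equal weight, while Cd163 stood at 79.8 and 62.7 CPM. In female cells none of 13 was higher (median 0.067, -0.046 to 0.12), and in male cells 3 were (median 0.19). Lipid and lysosome genes had 2 members higher of 15, Spp1 (45.4 and 75.5 CPM) and the lipoprotein lipase gene Lpl (167 and 254 CPM), and a median of 0.25 (0.19 to 0.30). None of 15 C1q and phagocytosis genes passed the rule, with a median of 0.11 (0.027 with thinned cells, -0.011 in female and 0.24 in male cells) and the Fc receptor gene Fcgr1 at 189 and 265 CPM. Monocyte-derived macrophage genes had 1 member higher and 2 lower of 9, with a median of -0.047 that ranged from -0.54 with the looser filter to 0.15 over members with at least 100 CPM. They were Ms4a4c (62.7 and 129 CPM), and Ly6c2 (28.6 and 5.50 CPM) and Plac8 (46.0 and 12.8 CPM), whose Fbn1 C1039G/+ UMIs lay in 6 and 4 cells. By sex this list had 3 higher and none lower of 7 in female cells (median 0.52). In male cells it had 1 higher and 6 lower of 10 (median -0.82). Ccr2, the receptor of monocyte recruitment, stood at 88.9 and 100.04 CPM. MHC class II genes had 1 member lower of 9, the regulator gene Ciita (65.3 and 39.4 CPM), and a median of -0.26 (-0.12 with cells clustered at resolution 0.5), with H2-Aa at 4414 and 3498 CPM.

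The largest ratios in macrophage-like cells were those of the histone genes Hist1h1d (7.57 and 30.8 CPM), Hist1h2ae (31.5 and 118 CPM) and Hist1h2ap (29.1 and 66.7 CPM), which dividing cells transcribe, and of Ctla2a and Isg20, with log2 ratios of 1.14 and 1.10. At the lower end S100a9 and S100a8, which are neutrophil and monocyte genes, had no UMI in the Fbn1 C1039G/+ library. They were 93.2-fold and 53.2-fold lower against the floor of 3 counts, with ratio intervals up to 0.0133 and 0.0234. All their wild type UMIs lay in 2 cells. Ly6i stood at 24.5 and 0.413 CPM and Ccl19 at 50.7 and 4.13 CPM, and the 5 wild type cells with most held 54.1% and 67.7% of their UMIs. In VIC-like cells Ccl19 was more abundant, at 255 and 138 CPM. Cluster 18, macrophage-like cells set apart by proliferation genes such as Mki67, Top2a and Hist1h2ae, held 79 wild type and 148 Fbn1 C1039G/+ cells. The other macrophage-like cluster, 7, held 742 and 753. Over the 20 measured cell cycle genes the median in macrophage-like cells was 0.20 (0.12 to 0.26), with 1 member higher. Whether a larger share of dividing cells accounts for the histone ratios was not tested, and histone genes were not left out of the clustering. By sex-linked transcripts 41.2% and 50.8% of macrophage-like cells were female and 37.3% and 27.2% male. The Y-linked gene Ddx3y stood at 41.6 and 23.0 CPM and Xist at 464 and 648 CPM. Hbb-bs stood at 46.7 and 242 CPM and Col1a1 at 151 and 123 CPM.

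The last comparison covered T cell-like cells, of which there were 145 and 107, with 870160 and 518986 UMIs. The genes with the largest ratios were mostly those of other cell types held by a few cells. Fn1, the fibronectin gene, stood at 1.15 and 210.0 CPM, and 1 cell held 76.1% of its UMIs in the Fbn1 C1039G/+ library. Mcpt2, a mast cell protease gene, stood at 296 and 7.71 CPM, and 1 wild type cell held 99.6% of its UMIs. Nupr1 (log2 ratio 4.91), Timp1 (4.07), Hspa1a (3.87) and Serpine2 (3.73) made up the rest of the upper end.

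At the lower end of T cell-like cells stood the proliferation genes Hist1h2ae (157 and 11.6 CPM), Hist1h4d (79.3 and 9.63 CPM), Hist1h1b (370.05 and 48.2 CPM) and Pclaf (329 and 52.0 CPM). Cluster 20 held 117 wild type and 45 Fbn1 C1039G/+ cells and cluster 11 held 28 and 62, so the class was made of different cells in the 2 libraries. Col1a1 stood at 319 and 1451 CPM, the antibody gene Igkc at 5515 and 0 CPM and Hbb-bs at 4545 and 46.2 CPM. Fbn1 stood at 25.3 and 90.6 CPM in this class. Timp1 and Serpine2 turned direction when the cell filter was made looser or stricter. Scaling by trimmed means moved the median of all genes in this class by -0.113 on the log2 scale and median-ratio scaling by -0.112.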

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

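The tests of heat shock members, of VEC-like cells for immediate early genes, of thinned cells, of interferon genes and VIC-like RNA in dendritic cell-like cells, of free RNA in macrophage-like and VEC-like cells and of single genes in VEC-like cells were chosen after the results were seen. The others were written before their own outcomes were seen, but for patterns that the comparisons had already shown. The test of Ecrg4, Col12a1 and Sfrp2 as 1 group uses genes among the 5 largest ratios in VEC-like cells.

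Unnamed clusters, which no comparison of genes used, held 1.41% of kept Fbn1 C1039G/+ cells against 0.284% of wild type cells (122 and 24 cells). Melanocyte-like cells, also outside the comparisons, had a median log2 ratio of -1.31 over the immediate early genes. In some lists female and male cells differed in opposite directions between the libraries, and these differences between the sexes were not tested. With 3 mice in the Fbn1 C1039G/+ pool 1 sex came from a single mouse, so sex cannot be told apart from the mouse. In VIC-like cells the chondrogenic and osteogenic median was -0.029 in female and 0.090 in male cells, and the cell cycle median was 0.51 and -0.34. In macrophage-like cells the heat shock median was 0.13 in female and -0.48 in male cells, the interferon median -0.18 and 0.48, and the monocyte-derived macrophage median 0.52 and -0.82.

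Immediate early transcripts such as Fos, Fosb and Atf3 were lower in VIC-like, macrophage-like, melanocyte-like and dendritic cell-like cells of the Fbn1 C1039G/+ library, with a median log2 ratio of -0.47 (-0.55 to -0.38) in the last. The tables argue against a handling difference of the same size in every class. Immediate early genes in VEC-like cells had a median of 0.13 (0.061 to 0.22), with 0.24 in female and -0.15 (-0.27 to 0.025) in male cells. In T cell-like cells, a class made of different cells in the 2 libraries, the median was 0.14 (-0.045 to 0.34). VEC-like levels were not corrected for RNA of other classes, so a smaller drop in that class is not excluded. There Fos stood at 190.1 and 179 CPM and the macrophage gene Lyz2 at 10.7 and 34.1 CPM. The tables also argue against mice of 1 sex, given medians of -0.87 in female and -1.24 in male VIC-like cells. With each cell thinned to 2000 UMIs the median was -1.16 (-1.20 to -1.11). Thinning keeps the expected proportions within a cell, so it argues only against the weight of deeper cells and cannot decide on depth otherwise. Kept cells had similar median depths, at 9753 UMIs in the wild type and 9723.5 in the Fbn1 C1039G/+ library. A weaker handling response shared by the whole list cannot be told apart, because its heat shock members, set apart after their values were seen, had medians of 0.13 (0.11 to 0.15) in VIC-like and 0.022 (-0.012 to 0.056) in macrophage-like cells. A difference in dissection or digestion time that acts on immediate early genes of some classes, or unequally by class, may still be the cause. It is confounded with genotype, as each genotype was prepared as 1 library, and an effect of the Fbn1 C1039G/+ genotype also stays open and was not tested.

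Interferon-stimulated transcripts such as Isg15, Bst2 and Ifi44 were higher in VIC-like cells of the Fbn1 C1039G/+ library, with medians of 0.19 in female and 0.43 in male cells that argue against mice of 1 sex as the cause. Within single VIC-like clusters the list median ranged from -0.25 to 0.62. In cluster 6, led by Ifit3, Ifi44 and Isg15, it was -0.22, while that cluster held 220 wild type and 705 Fbn1 C1039G/+ cells. Interferon genes lead cluster 6 and were not left out of the clustering, so its share and its list median are not independent. The higher level in the class joins shares of clusters with differences within them, and how much each adds cannot be told apart here. A state of VIC-like cells alone is argued against by dendritic cell-like cells, with a median of 0.41 (0.27 to 0.83), 7 of 15 members higher and medians of 0.42 (0.012 to 0.73) and 0.88 (0.61 to 1.10) in their clusters 19 (34 and 57 cells) and 21 (65 and 54 cells), whereas the medians of VEC-like, macrophage-like and T cell-like cells were 0.12, -0.069 and -0.25. RNA of VIC-like cells is argued against as the source of the dendritic gain, which needed a median of 15.1% of the VIC-like level, because 53 abundant VIC-like transcripts had a median gain of -1.34% there. Free RNA from VIC-like cells cannot be told apart in macrophage-like cells, because the 16 members measured in both classes had a median gain of 4.91% of the VIC-like level with quartiles of -20.4% and 38.1%, and the form of this test written before took only members with a gain in both classes, which fixed its outcome. A single exposed mouse would be of 1 sex, which the medians by sex in VIC-like cells argue against. In macrophage-like cells the median was -0.18 (-0.33 to -0.025) in female and 0.48 (0.31 to 0.60) in male cells, so a single mouse is not argued against there. Interferon exposure of pooled mice of both sexes may be behind the pattern and so may the genotype, and neither was tested.

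Some transcripts of interstitial cells, among them Ecrg4 and Col12a1, were higher in VEC-like cells of the Fbn1 C1039G/+ library. Free RNA that reached both classes alike is argued against for Ecrg4, Col12a1, Sfrp2, Col1a1 and Col1a2 as a set. Their median gain in macrophage-like cells was -0.13 of that in VEC-like cells, though Ecrg4, Col12a1 and Sfrp2 were picked by their VEC-like ratios. Other foreign RNA is not excluded, as Hbb-bs was higher in VEC-like (23.5 and 413 CPM) and macrophage-like cells (46.7 and 242 CPM). Outside the VEC-like class, unnamed cluster 14 carried markers of both VIC and VEC and held 1 wild type and 22 Fbn1 C1039G/+ cells. VIC-like cells stuck to VEC-like cells would bring a median of 3.24% of VIC-like RNA, judged from 20 abundant transcripts, and shares within 2-fold of that were needed for Ecrg4 (4.98%), Sfrp2 (4.10%), Sox9 (4.29%) and Tagln (2.26%, itself 1 of the 20), so these gains may come from stuck cells. Larger shares were needed for Col12a1 (52.8%), Cdh2 (25.7%), Acta2 (16.9%) and S100a4 (15.7%), which argues against stuck VIC-like cells as their whole cause, while Ecrg4, Col12a1 and Sfrp2 taken as 1 group were left undecided. A VIC-like state richer in these transcripts, another cell type and an effect of genotype on endothelial cells stay open, and none was tested.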

How the results depend on the processing

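Leaving out VIC-like clusters 2, 3 and 5 and clustering without differing genes were chosen after seeing the data, and the other alternatives before. Each alternative changed 1 choice, except that the looser cell filter also led to another doublet rule in the wild type library, so its values join both. A value was counted as moved when it left the counting interval of the reported value, and as turned when its sign changed and that interval had excluded 0. Medians of cell cycle, Notch, BMP, Wnt and monocyte-derived macrophage genes, with intervals that included 0, also changed sign and are among those that moved. Of the values for cell shares, Fbn1, gene lists and VIC-like clusters 321 stayed, 87 moved and 2 turned direction. Of the values for single genes 1440 stayed, 428 moved and 9 turned. Differences of the VIC-like, VEC-like and macrophage-like shares, Fbn1 in VEC-like cells and the TGF-beta, endoplasmic reticulum and lymphatic-type medians stayed within their intervals under each alternative run. So did all list medians under median-ratio scaling. Intervals for VIC-like cells are narrow because 72455537 and 74512376 UMIs stand behind them, so small shifts count as moved. Depth limits T cell-like cells most, with 870160 and 518986 UMIs. No paired analysis was possible because each genotype had 1 library. T cell-like cells gave no values with each library clustered alone. Thinning left out 16 and 123 VIC-like, 9 and 3 VEC-like, 24 and 31 macrophage-like and 5 and 6 T cell-like cells under its depth. Values that moved follow, as median log2 ratios of lists unless named otherwise. The cause was not tested for any of them, apart from the level filters, which by construction change the genes in a list. Thinning also changed the genes measured, from 7227 to 4628 in VEC-like and from 3968 to 1408 in T cell-like cells, so its list medians can rest on fewer members.

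With all cells clustered at resolution 0.5 collagens had 0.27 and MHC class II -0.12, and at resolution 2 they had 0.28 and -0.12. TMM scaling gave 0.22 for collagens. With all genes used, the dissimilarity of VIC-like clusters was 16.97 points at resolution 0.5, 11.5 at 0.3 and 21.8 at 1. With each library clustered alone Fbn1 in VIC-like cells had a log2 ratio of 0.15, collagens 0.28, contractile genes 0.22, MHC class II -0.33, resident macrophage 0.0005, inflammatory mediators -1.19 and lipid and lysosome genes 0.18. The looser cell filter gave collagens 0.29, proteases 0.15, interferon 0.36, cell cycle -0.12, MHC class II -0.21, resident macrophage 0.22, monocyte-derived macrophage -0.54, inflammatory mediators -1.16 and C1q 0.22. The stricter filter gave cell cycle -0.095. With doublets kept proteases had 0.15, cell cycle -0.12, MHC class II -0.29 and monocyte-derived macrophage 0.058.

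With cells thinned to 2000 UMIs Fbn1 in VIC-like cells had 0.16, fibrillin genes 0.13, collagens 0.29, proteoglycans 0.042, proteases 0.17, chondrogenic genes 0.15, complement -0.20, interferon 0.37, cell cycle -0.042, the dissociation and immediate early list -0.65, glycolysis 0.066, shear stress 0.0090, endothelial-to-mesenchymal 0.042, MHC class II -0.22, inflammatory mediators -1.44 and C1q 0.027. The mean of per-cell CPM gave Fbn1 in VIC-like cells 0.16, fibrillin genes 0.12, proteoglycans 0.057, Wnt 0.022, proteases 0.18, chondrogenic genes 0.14, complement -0.23, interferon 0.38, the dissociation and immediate early list -0.67, oxidative phosphorylation 0.021, glycolysis 0.054, shear stress 0.079, MHC class II -0.20, resident macrophage 0 and monocyte-derived macrophage 0.081.

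A level filter of 100 CPM gave BMP -0.043, proteases 0.20, contractile genes 0.21, chondrogenic genes 0.098, chemokines -0.52, complement -0.17, interferon 0.66, cell cycle 0.15, the dissociation and immediate early list -0.71, Notch 0.15, endothelial-to-mesenchymal 0.096, MHC class II -0.21, monocyte-derived macrophage 0.15 and inflammatory mediators -0.90. Without a level filter Wnt had -0.099, proteases 0.0096, contractile genes 0.13, cell cycle 0.13, MHC class II -0.30 and inflammatory mediators -1.44, and proteoglycans turned to -0.050. A pseudocount of 10 CPM gave chemokines -0.33 and the dissociation and immediate early list -0.59. Without VIC-like clusters 2, 3 and 5 Fbn1 had 0.051, collagens 0.22, proteases 0.10, chemokines -0.49, complement -0.42 and the dissociation and immediate early list -0.51, and proteoglycans turned to -0.028.

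Single genes turned as follows, in log2 ratios. In T cell-like cells Serpine2 had -0.64 at resolution 2, -1.27 with the looser and -0.59 with the stricter filter, and Timp1 -3.02 and -2.87 with these filters. In VEC-like cells Jag1 had 0.34 with thinned cells and Adm -0.15 with the mean of per-cell CPM. In macrophage-like cells Ccr2 had -0.037 with thinned cells and -0.0080 with doublets kept.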

Other observations

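The genes in the next paragraph were chosen after their values were seen, while both tests that follow were written before their own outcomes were seen. The second takes the 3 genes with the smallest ratios in VEC-like cells, so it was framed after those ratios were seen.

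VIC-like cells of the Fbn1 C1039G/+ library also had higher levels of genes outside the named groups. Fn1, the fibronectin gene, stood at 79.0 CPM in the wild type and 164 CPM in the Fbn1 C1039G/+ library. Inhba, which encodes a subunit of activin, the ligand bound by follistatin, stood at 45.3 and 71.1 CPM, and the cell cycle inhibitor gene Cdkn1a at 206 and 352 CPM. All 4 measured genes of the MHC class II list were lower in VIC-like cells of the Fbn1 C1039G/+ library, with Cd74 at 107 and 60.2 CPM, H2-Aa at 46.7 and 28.7 CPM, H2-Ab1 at 75.8 and 49.0 CPM and H2-Eb1 at 49.3 and 32.4 CPM. The macrophage gene Lyz2 stood at 13.1 and 17.7 CPM in the same cells. Nrgn (74.8 and 35.1 CPM) and Bglap2 (161 and 76.3 CPM) were lower as well. When VIC-like cells were clustered with all genes, these genes of MHC class II, Nrgn, Bglap2, Sez6l and Mal led the same cluster. It held 19.8% of wild type and 11.3% of Fbn1 C1039G/+ VIC-like cells. The 10 leading genes of this cluster all differed at least 1.5-fold between the libraries and were not left out when it was built. Its share and their levels are therefore not separate findings. Levels within the cluster were not compared, so a smaller share of 1 cell state and lower levels within it cannot be told apart. Hemoglobin transcripts went in different directions by class, with Hbb-bs at 766 and 441 CPM in VIC-like, 23.5 and 413 CPM in VEC-like, 46.7 and 242 CPM in macrophage-like and 4545 and 46.2 CPM in T cell-like cells.

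One hypothesis was that DNA of another mouse strain, carried along with the Fbn1 allele, changed genes beside it. Over 73 measured genes within 10 Mb of Fbn1 on chromosome 2 the median size of the log2 ratio in VIC-like cells was 0.077, against 0.084 over all genes. It lay at percentile 29.3 of matched random lists, which argues against such an effect over this flank as a whole. A median does not respond to changes in a few genes, so an effect on single genes of the flank is not excluded. In this flank Mal (45.8 and 28.0 CPM) passed the 1.5-fold rule, and Thbs1 stood at 1376 and 1905 CPM. Mal was also a leading gene of the smaller VIC-like cluster led by Nrgn and genes of MHC class II.

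Another hypothesis was that Mmrn1, Ccl21a and Reln in wild type VEC-like cells came from a small set of cells of another type. Cells with at least 5 UMIs of these genes held 99.95% of their UMIs. This share alone cannot decide, because 2048 UMIs spread evenly over 274 cells would also lie mostly in such cells. Only 4 of the 274 cells passed this threshold, as 4 lymphatic endothelial cells inside the class would give. Whether such cells were missing from the Fbn1 C1039G/+ valves or were not sampled cannot be decided, since 0 of 406 cells allows a share of up to 0.904% and 4 of 274 is 1.46% (0.399 to 3.70).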
